A study of Mus musculus with 2 samples.

How the data were processed

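Total RNA from wounded skin was hybridised to Illumina single-colour mouse bead arrays, with biotin-labelled cDNA detected by Cy3-streptavidin, per the labels' protocols. There were 2 arrays, 1 of control and 1 of Vdr knockout skin, on 1 slide per the file headers. The series' design text speaks of 3 per genotype with RNA of 3 mice in each sample. Here it was read as 1 pool of 3 mice per array, 6 mice in all, and other samples were not analysed here. The grouping follows the sample titles. Scanner data were processed with GenomeStudio 2011.1, per the submitters' processing notes. The background and normalization methods are not given in the sources used here.

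Each array had 25697 probes in 3 tables. The deposited raw table holds the average bead signal per probe as a linear intensity without background subtraction, running from 126.9 to 44195 on the control array and from 113.8 to 39675 on the knockout array. The deposited normalized table holds intensity after the authors' normalization between arrays: both columns have the same quantiles, with 0.0% of ranks differing by over 1%. Its highest value is 0.983 of the mean of the highest raw values, so the reference distribution was not the unscaled mean of these 2 arrays. Whether it was that mean times a constant was not tested. The series matrix equals the normalized table, with 0 probes differing. It is linear, is not centred and has a median of 169.9 in each column.

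Both deposited tables also carry a detection p-value per probe from GenomeStudio, and these columns were found not to follow the row order of the signals. The rank correlation of signal with p-value was 0.009 on the control array and 0.008 on the knockout array, where a value near -1 is inherent to the measure. Between arrays the p-values correlated at 0.91 and the signals at 0.93, and the signals fit the gene names of their rows, with keratins bright and olfactory receptors dim. Sorting the rows by the other columns did not restore the order. The p-values were therefore used as a set per array only. On each array the probes counted as detected were as many of the brightest as there were p-values under 0.01, which gave 12588 probes (49.0%) above a raw signal of 182.7 in the control and 12161 (47.3%) above 172.9 in the knockout. In the normalized values these floors are 172.2 and 176.7. As a check, of 1332 olfactory and vomeronasal receptor probes, silent in skin, 0.53% and 0.45% lay above the floors.

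The design fixed before the data were examined had limma's neqc on the raw table with its detection p-values as main, and the authors' normalized table if that could not be used. Since the p-values are out of order, the main values are log2 of the authors' normalized intensity with no offset. The neqc result, with p-values reassigned by rank of signal, is an added alternative. It gives about 2 times as many genes past 2-fold, and its counts stand beside the main ones in the report. Because background remains in the main values, folds of dim genes are understated. These choices were made after seeing the data: the rank-based floor, neqc with reassigned p-values, a floor from receptor probes, the size of difference between settings counted as moved (0.58 on the log2 scale, 1.5-fold) and all tests of explanations. Background correction in the other alternatives used the reassigned p-values too.

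A gene was represented by its brightest probe by mean over both arrays. Of the probes, 25376 were named through a RefSeq gene table of GRCm38.p6, 16938 by Entrez identifier, 7420 by accession, 465 by symbol and 553 by synonym, and 321 kept the name in the file. Coordinates are not printed, since the build behind the tables is not given in the sources used here. A gene detected on 1 array only has a bound: its value there against the higher of the other array's floor and the gene's own value. Its difference entered list medians as measured, and medians with bounds are given where they differ. For 20 genes the probes disagreed on detection, and they were left out of the counts of genes past 2-fold. Among the named genes with several detected probes (44), those of Itgae, Pmel and Shh differed by over 1 on the log2 scale.

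With 1 array per group no test was run. Genes past 2-fold were counted among those detected on both arrays. For 30 gene lists fixed beforehand, covering vitamin D, Wnt, hedgehog, hair follicle, keratinocyte, immune, stromal and other tissue markers, the median log2 difference of detected members was placed among the medians of 10000 random lists of the same size, matched on deciles of mean expression. Lists with under 5 detected members got no percentile. Random lists are drawn gene by gene, so genes of 1 tissue that shift together can leave their central range through a difference in tissue amounts alone. A percentile therefore does not tie a shift to the genotype. Some lists overlap: the antimicrobial and neutrophil lists share S100a8 and S100a9, the protease and neutrophil lists Mmp8 and Mmp9, the Wnt and stem cell lists Lgr5, the vitamin D and calcium lists Trpv6, and the vitamin D and antimicrobial lists Camp. The genes named were Vdr, the 12 with the greatest difference in each direction among those detected on both arrays, the 5 with the greatest bound in each direction, and in each list up to 4 members with the greatest difference and the brightest one. Symbols without a gene name were passed over, which concerned 1 gene among the lower bounds. Other genes named, such as members that explain a count or a bound, were chosen after their values were seen.

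The counting and the list percentiles were tested on simulated data for this comparison, with 200 of 17871 genes changed. At a true fold of 1.5, 2.5, 4 and 8, 2.0%, 94.0%, 100% and 100% of 50 genes each were called at 2-fold, and 0 of 8891 unchanged genes. A list raised 1.5-fold reached percentile 100, and 4.0% of 100 unchanged lists lay outside the central 95%. The simulated noise was independent between probes, with the robust spread of the measured differences between the 2 arrays. These shares therefore say nothing about differences between mice or pools, which can shift many genes together. The changed genes were all bright on the control array, and their folds were added directly to the normalized values. The shares of changed genes called therefore do not cover dim genes, whose folds the background understates. The alternatives were no background correction with an offset of 16, background correction followed by median scaling, cyclic loess or quantile with an offset of 50, the series matrix, a p-value threshold of 0.05, no detection filter, the mean of a gene's detected probes, a 1.5-fold threshold and the mean of a list. Computations used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.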

Results

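Gene expression was measured in wounded back skin of 3-month-old C57BL6 mice on a low calcium diet, 3 days after wounding. In the knockout mice the vitamin D receptor gene Vdr, floxed in these animals, was removed by Cre recombinase in cells that express keratin 14, the keratin of basal keratinocytes. Littermates served as controls. Each mouse received 2 full-thickness punch wounds of 6 mm, and the wounded skin was cut out with an 8 mm punch, so that each sample held wound, wound edge and surrounding skin with all its cell types. The data are 2 Illumina bead arrays, 1 of control and 1 of knockout wounded skin, and per the series' design text each sample holds RNA of 3 mice. With 1 array per group no difference below has a replicate check, a test or a p-value. The number of arrays limits the precision. Differences are given as log2 intensity, knockout minus control, and describe these 2 arrays.

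Of 17871 genes on the array, 8934 were detected on both arrays, 538 on the control array only and 261 on the knockout array only. The median raw signal was 180.0 on the control array and 165.8 on the knockout array, and 169.9 on each after the authors' normalization. Across the genes detected on both arrays, the log2 difference had a median of 0.02, and the central 95% of genes lay between -0.58 and 0.65. Probes of the same gene differed in this value with an SD of 0.14 over 2131 genes, which measures probe noise and not the spread between mice.

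The comparison of knockout with control skin asks how loss of the receptor in keratinocytes relates to gene expression in the healing wound, with epidermal stem cells named as a subject in the series title. Vdr itself had an intensity of 2596 on the control array and 2076 on the knockout array, 1.25-fold lower in the knockout. A different Vdr probe gave 1674 and 1430, and the remaining one 212 and 217, little above the detection floor. Whether these probes lie in the deleted part of the gene is not known here, and cells of the dermis keep the gene by design, so that this difference is a weak check of the labels. The list of vitamin D genes, which includes Vdr, showed no common direction. Of its 9 detected members, 5 were higher and 4 lower, all within 1.5-fold, with a median of 0.00 at percentile 48.57 of 10000 random lists matched on expression. Cyp27a1, a vitamin D 25-hydroxylase, was at 705 and 999, and Hr, the hairless corepressor that binds the receptor, at 7664 and 9595. Cyp24a1, the enzyme that inactivates vitamin D, was detected on the control array only, at 191, near the floor.

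Genes of the growing hair follicle were far lower in knockout wounded skin, genes of pigment cells were lower as well, and interferon-response, antigen-presentation, lymphoid and sebaceous gland genes were higher. Among genes detected on both arrays, 66 were at least 2-fold higher and 80 at least 2-fold lower in the knockout. The lower genes held the large differences: 32 were at least 4-fold lower and 21 at least 8-fold lower, against 1 and 0 in the higher direction. A further 55 genes detected on the control array only were lower by a bound of at least 2-fold, against 1 higher gene among those detected on the knockout array only. With background correction by neqc the counts were 158 higher and 142 lower, and these held all 66 and all 80. The authors' values keep the background, so folds of dim genes are understated.

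**Figure D1:**
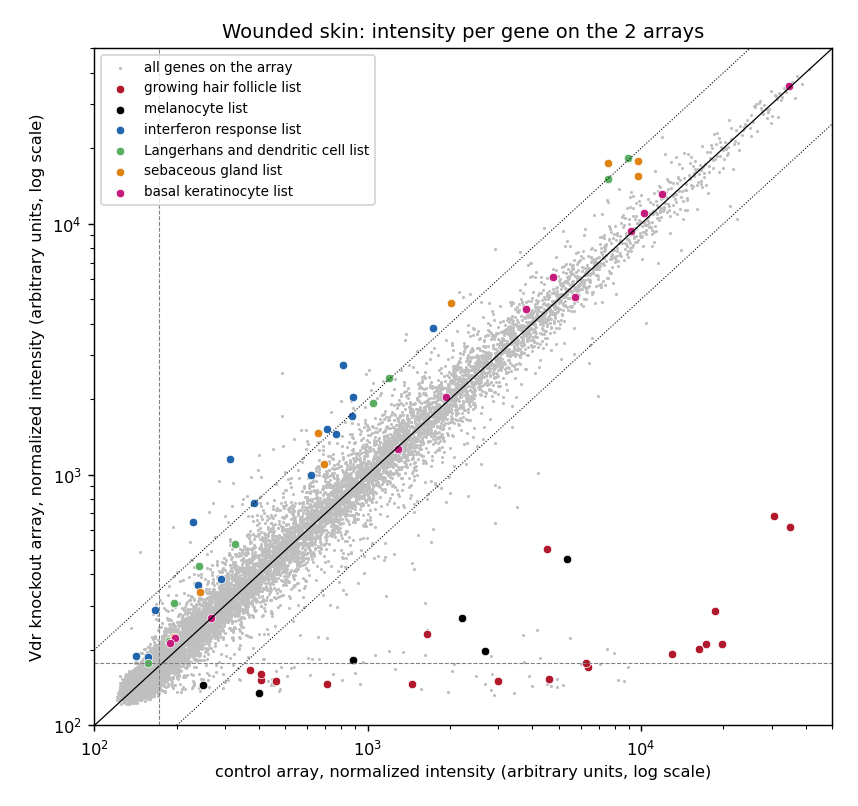
Normalized intensity of each gene on the control array (horizontal axis) and the Vdr knockout array (vertical axis), arbitrary units on log scales, with members of 6 gene lists in colour, the line of equal intensity, dotted lines at 2-fold and dashed lines at the detection floors of 172.2 and 176.7. Hair follicle and melanocyte genes lie far below the line of equal intensity, basal keratinocyte genes lie along it, and interferon, Langerhans and dendritic cell and sebaceous gland genes lie above it.

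All 19 detected members of the growing (anagen) hair follicle list were at least 2-fold lower in the knockout, with a median of -4.91, or -4.70 with undetected genes at their bound, below all 10000 random lists. The hair shaft keratins Krt34, Krt33a and Krt86 had intensities of 19741, 17223 and 12994 in control skin and of 212, 212 and 192 in knockout skin, differences of 93.2-fold, 81.4-fold and 67.7-fold. Keratins of the inner root sheath, the layer that moulds the hair, followed the same direction: Krt73 was 65.2-fold lower, Krt71 was at 34898 and 618, and Krt27 at 30589 and 686. S100a3, a calcium-binding protein of the hair cuticle, was 81.2-fold lower and Krt31 35.4-fold lower. Dlx3, a homeobox factor of hair differentiation, was at 4523 and 506. The remaining genes among the 12 with the greatest difference downwards were Vsig8, Prr9, Cryba4 and Ly6g6d, lower by 40.9-fold, 37.3-fold, 24.7-fold and 22.9-fold. Of these 12 genes, all but Krt71 and Krt27 moved by over 1.5-fold with background correction, to lower values. On the log2 scale Krt34 went from -6.54 to as low as -7.77, S100a3 from -6.34 to -7.73, Krt31, at 177.4 in the knockout against a floor of 176.7, from -5.15 to -6.96, and Ly6g6d from -4.52 to -6.15. The folds given are therefore exact for the authors' values only.

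Hair genes also led the named genes detected on the control array only, with 1 symbol without a gene name, A030003K21Rik, passed over among them. Krtap19-9b and Krtap16-3, matrix proteins of the hair shaft, were at least 48.9-fold and 46.7-fold lower in the knockout, the trichohyalin relative Tchhl1 at least 40.1-fold, the inner root sheath keratin Krt26 at least 36.3-fold and the thyroid-hormone-binding protein Crym at least 34.2-fold. Of 28 detected keratin-associated protein (Krtap) genes, all 28 were lower in the knockout, under each scaling tried too. Without a detection filter 30 of 32 were. Keratin and Krtap genes made up 28 of the 55 genes with a bound of at least 2-fold and 9 of the 80 genes measured on both arrays. After background correction by neqc the median of the hair follicle list was -6.14.

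Melanocyte genes were lower together. Of 6 detected members 5 were at least 2-fold lower, and Slc45a2, not detected in the knockout, at least 1.41-fold lower, with a median of -2.66, below all 10000 random lists. Dct, an enzyme of melanin synthesis, was at 5377 in control and 461 in knockout skin, and Tyrp1, another, at 883 and 182. Mlana, a melanosome protein, was 8.25-fold lower. Pmel, which forms the fibrils of the melanosome, was at 2686 and 199, while its dimmer probe differed by -2.71 and was below the floor in the knockout. The list's median was -3.80 with neqc and -1.57 without a detection filter.

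Stem cell markers had a slightly lower median in the knockout, and single Wnt genes were lower. Whether the Wnt, hedgehog and stem cell differences are separate from the fall of the growing hair follicle list, with its median of -4.91, was not tested. Of 15 detected Wnt/beta-catenin targets, 3 were at least 1.5-fold lower and none as much higher, with a median of -0.21 at percentile 0.01 of random lists. With undetected genes at their bound the median was -0.01, since Lef1, Tcf7 and Notum lay near the floor on the control array. This lies between -0.12 and 0.14, the limits of the central 95% of random lists, which were computed without bounds. A bound is the least possible change, so with bounds the shift of the Wnt list as a group is not secured. As measured, the list's median ran from -0.67 to -0.12 over the alternatives. Nkd2, a feedback inhibitor of Wnt signalling, was at 1168 and 327, the secreted inhibitor Wif1 at 413 and 184, cyclin D1 (Ccnd1) at 5203 and 3347 and Apcdd1, another inhibitor, at 1117 and 747. Only 4 hedgehog genes were detected, with a median of -0.34, and all were lower. Shh, the ligand of hair follicle growth, was at 474 in control skin and at least 2.68-fold lower in the knockout, with a second probe at 176.8 and 156.4, and Smo, the signal transducer, was at 893 and 660, while its dim probes differed by 0.09 and -0.09. Hair follicle and epidermal stem cell markers, which share Lgr5 with the Wnt list, had a median of -0.21 over 12 genes, at percentile 0.14. Of these only Tbx1, a bulge transcription factor, passed 1.5-fold, at 1051 and 463. Krt15, a bulge keratin, was at 5119 and 4374, Tcf7l1 at 1825 and 1276, and Krt24, in the other direction, at 280 and 390.

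Basal keratinocyte genes were close between the arrays, and the medians of the differentiation and wound-activated lists were slightly higher in the knockout. All 12 detected basal keratinocyte and hemidesmosome genes were within 1.5-fold, with a median of 0.09 at percentile 84.94: Krt14 was at 34643 and 35507, and the hemidesmosome integrin Itgb4 at 4767 and 6149. Of 24 epidermal differentiation genes, 15 were higher and 9 lower, 4 were at least 1.5-fold higher and none as much lower, with a median of 0.14 at percentile 98.79. The 4 were Casp14, a caspase of cornification, at 8281 and 13749, the lipoxygenase Alox12b at 695 and 1112, and the cornified envelope genes Lce1c and Lce1b, 1.61-fold and 1.52-fold higher. Wound-activated keratinocyte genes had a median of 0.15 over 17 genes, at percentile 97.59. Krt17, a keratin of activated keratinocytes, was at 27206 and 30915, and only Sprr2f, a cornified envelope precursor, passed 1.5-fold, at 428 and 773.

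Cell cycle genes were slightly lower, 20 of 25 of them, all within 1.5-fold, with a median of -0.13 at percentile 0.31, or -0.12 with bounds. Their shift, too, was not separated from that of the growing hair follicle genes. Thymidine kinase Tk1 was at 1259 and 893, with a dim probe at 217 and 226, and cyclin B1 (Ccnb1) at 833 and 594. Calcium-sensing and adherens junction genes had a median of 0.08 over 13 genes, at percentile 83.36, all within 1.5-fold. Ctnnb1, which encodes beta-catenin, was at 3512 and 2628, and Ctnna1, its partner alpha-catenin, at 13211 and 11094. TGF-beta and activin genes had a median of 0.02 over 13 genes, at percentile 49.77, with the activin subunit Inhba at 351 and 487.

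**Figure D2:**
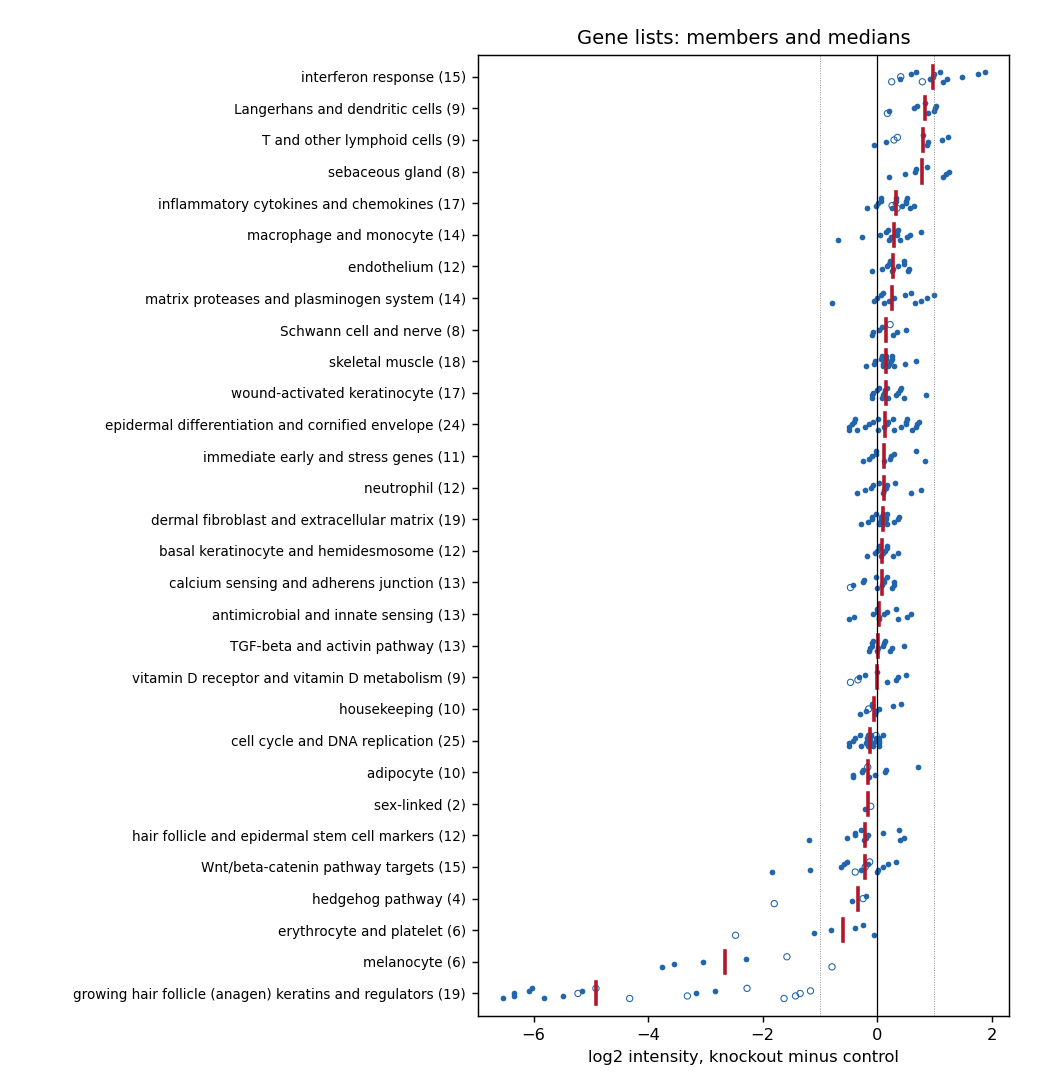
Log2 intensity difference, knockout minus control (horizontal axis), of the detected members of each of the 30 gene lists (rows, with the number detected), filled for genes detected on both arrays and open for the others, with red bars at the medians and dotted lines at 2-fold. The hair follicle and melanocyte lists have medians of -4.91 and -2.66, and the interferon list has the highest median, 0.97.

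Interferon-response genes were higher in knockout skin, all 15 detected members, with 12 at least 1.5-fold and 7 at least 2-fold higher. Their median of 0.97 lay above all 10000 random lists. Isg15, a ubiquitin-like protein induced by interferon, was at 810 in control and 2743 in knockout skin, and Usp18, the protease that removes it, at 880 and 2041. Cxcl9 and Cxcl10, chemokines for activated T cells, were 3.68-fold and 2.81-fold higher, and the guanylate-binding protein Gbp2 was 2.23-fold higher. Mx2, an antiviral GTPase, was detected on the knockout array only, at least 1.68-fold higher.

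Antigen-presentation and lymphoid genes were higher on the same array. Of 9 detected Langerhans and dendritic cell genes, 7 were at least 1.5-fold and 3 at least 2-fold higher, with a median of 0.84 above all 10000 random lists. Cd74, the invariant chain of MHC class II, was at 8969 and 18239, the class II chain H2-Ab1 at 7558 and 15139, and H2-DMa, which loads peptide, at 1201 and 2421. Of 9 detected lymphoid genes, 5 were at least 1.5-fold higher, with a median of 0.81, above all 10000 random lists, or 0.14 over all list members without a detection filter. The 1 detected member that was lower, Lck, was at 270.5 and 260.2. Cd3g and Cd3e, chains of the T cell receptor complex, were 2.20-fold and 1.85-fold higher, and Nkg7, a cytotoxic granule protein, 1.83-fold. Itgae, the integrin of epidermal T cells, was at 317 and 751, but its probes disagreed: the 2 bright ones differed by 1.24 and 1.16 and the 2 dim ones by 0.15. Genes detected on the knockout array only included the lymphocyte genes Cd8b1 and Xcl1, at least 1.62-fold and 1.67-fold higher.

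Other leukocyte and wound genes differed less. Macrophage and monocyte genes had a median of 0.29 over 14 genes, at percentile 99.96, with Ms4a7 at 1634 and 2782, lysozyme Lyz2 at 14833 and 18923, and Chil3 in the other direction at 1022 and 636. Neutrophil genes had a median of 0.12 over 12 genes, at percentile 90.86. S100a8, an abundant neutrophil and keratinocyte protein, was at 27568 and 28157, and only the receptor Trem1 and the protease Mmp9, 1.51-fold and 1.71-fold higher, passed 1.5-fold. Inflammatory cytokines and chemokines had a median of 0.33 over 17 genes, at percentile 99.99, or 0.32 with bounds. Among them only the chemokine Ccl7 passed 1.5-fold, at 497 and 776, and the alarmin Il33 was at 2435 and 3610. Antimicrobial and innate sensing genes had a median of 0.03 over 13 genes, at percentile 61.03, all within 1.5-fold, with Lcn2, which binds siderophores, at 4095 and 6142. Of 14 matrix proteases and inhibitors, 5 were at least 1.5-fold higher and 1 lower, with a median of 0.26 at percentile 99.92. The macrophage elastase Mmp12 was at 196 and 392, the collagenase Mmp13 at 1748 and 3191, and the inhibitor Timp3 at 2659 and 1542.

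Sebaceous gland genes were higher, all 8 detected members, with 6 at least 1.5-fold and 3 at least 2-fold. Their median of 0.78 lay above all 10000 random lists. Fa2h, a fatty acid hydroxylase, was at 7583 and 17386, the lipid droplet protein Cidea at 2018 and 4826, and the fatty acid elongases Elovl3 and Elovl4 were 2.22-fold and 1.84-fold higher. The genes with the greatest difference upwards outside these lists were Serpinb6d, a protease inhibitor of the serpin family, at 488 and 2540, Sec14l4 at 486 and 1714, and Sgpp2, a sphingosine-phosphate phosphatase, at 285 and 944. Erdr1 was 3.17-fold, the MHC class I relative H2-M2 3.00-fold, Aadacl4 2.87-fold, Pnpla5 2.85-fold, Pdss1 2.82-fold and the serpin Serpina3b 2.70-fold higher. Among genes detected on the knockout array only, the beta-defensin Defb8 was at least 2.84-fold and Scgb1b27 at least 1.77-fold higher.

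**Figure D3:**
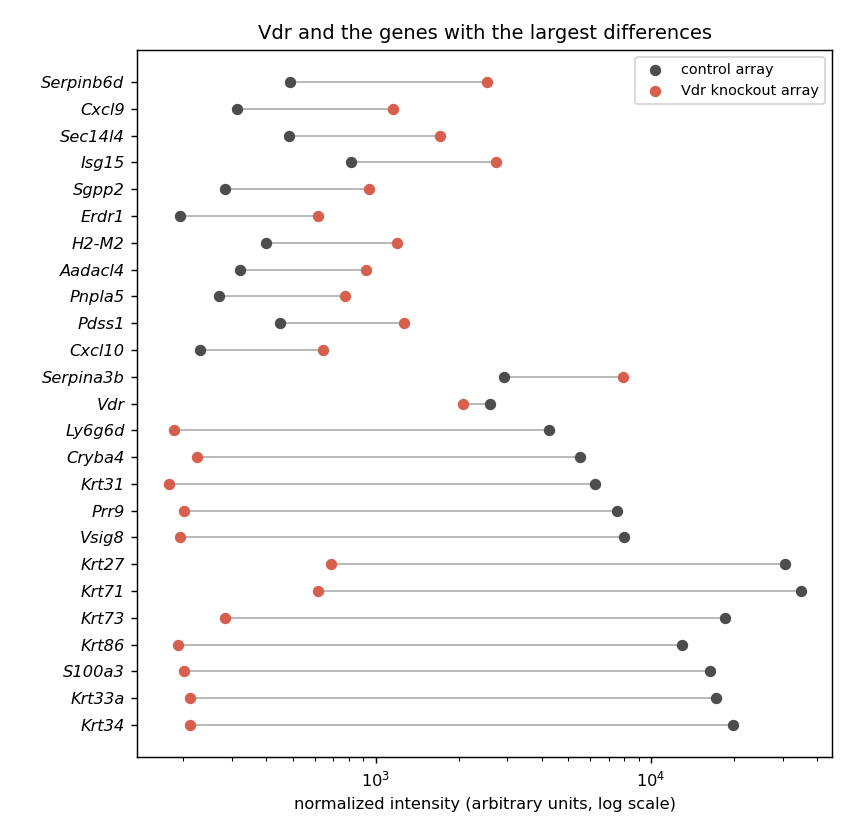
Normalized intensity (arbitrary units, log scale) of Vdr and of the 12 genes with the greatest difference in each direction, on the control array (grey points) and the Vdr knockout array (red points), with 1 array per group and hence no error bars. Krt34 is at 19741 in control and 212 in knockout skin, and Serpinb6d at 488 and 2540.

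Markers of other tissue components were set beside these. Dermal fibroblast and matrix genes had a median of 0.10 over 19 genes, at percentile 92.17, all within 1.5-fold, with the collagen Col1a1 at 9086 and 11691. Endothelial genes had a median of 0.28 over 12 genes, at percentile 99.86, all within 1.5-fold, with the coreceptor Eng at 702 and 1035. Skeletal muscle genes had a median of 0.16 over 18 genes, at percentile 98.93, and the myosin Myh1, at 606 and 972, was the one beyond 1.5-fold. The medians of the differentiation and wound-activated lists, 0.14 and 0.15, were no larger than this. Shifts of that size may reflect the amount of each tissue in the 2 samples, which was not measured. Adipocyte genes had a median of -0.15 over 10 genes, or -0.09 with bounds, at percentile 1.76, with adiponectin (Adipoq) at 2134 and 1594 and the regulator Pparg, also expressed by sebocytes, at 658 and 1080. Schwann cell and nerve genes had a median of 0.16 over 8 genes, at percentile 97.44, or 0.07 with bounds. Myelin basic protein (Mbp) was at 519 and 741 by its brightest probe and, in the other direction, at 487 and 454 by another. Of 6 erythrocyte and platelet genes, all were lower and 3 by at least 1.5-fold, with a median of -0.59 at percentile 0.01. Haemoglobin alpha (Hba-a1) was at 22377 and 10408, and Slc4a1, the red-cell anion exchanger, at least 5.07-fold lower. Immediate early genes had a median of 0.12 over 11 genes, at percentile 89.3, with the transcription factors Egr2 and Atf3 1.78-fold and 1.60-fold higher. Housekeeping genes had a median of -0.06 over 10 genes, at percentile 16.2, all within 1.5-fold, with Ppia at 29426 and 28556. Of the sex-linked genes only the Y-linked Ddx3y, at 741 and 642, and Xist, at 178 and 165, were detected, Xist on the control array only and near the floor.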

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

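Alternatives run comprised 10 chosen before the data were examined and 2 chosen after seeing the data, neqc and the receptor-probe floor. Those of the 10 with background correction were run with p-values reassigned by rank of signal. All of the 10 but the one without a filter used the rank-based floor. Both steps were settled after seeing the data. No paired analysis was possible because each group has 1 array, which also rules out leaving out arrays. In 318 of 330 comparisons of a list median the value moved by less than 0.58 on the log2 scale. The same held for 1708 of 1858 comparisons of 186 genes named in the report or the observations. No list or gene among these that was called changed sign. The series matrix equals the main values, so its comparisons could not move. A changed detection filter alone leaves the difference of a single gene as it was. The shares include these fixed outcomes and so overstate the stability. Of the 186 genes, only Pmp22 (-0.07) had the opposite sign under 1 of 10 alternatives. The Vdr difference ranged from -0.42 to -0.17. Genes at least 2-fold higher numbered 122 with median scaling, 138 with cyclic loess, 109 with an offset of 50, 158 with neqc and 317 at 1.5-fold. Genes at least 2-fold lower numbered 174 with median scaling, 152 with cyclic loess, 142 with neqc, 140 without a detection filter and 224 at 1.5-fold. With the offset and quantile normalization of neqc but no background correction, the counts were 55 higher and 77 lower. Median scaling and cyclic loess changed the normalization along with the background, and for their counts the cause was not tested. The 1.5-fold counts come from a lower threshold, and without a filter genes undetected on the knockout array enter the count. The hair follicle median was -6.16 with median scaling, -6.13 with cyclic loess, -5.67 with an offset of 50, -6.14 with neqc, -4.32 without a filter and -4.18 as a mean. The melanocyte median was -3.86, -3.80, -3.35, -3.80 and -1.57 under the same settings up to no filter. The lymphoid median was 0.14 without a filter, where genes undetected on both arrays enter the list. Median differences of all genes on both arrays lay between -0.04 and 0.03 over all settings but those of threshold and list mean. Signal over background limits what can be seen: 8118 genes were detected on neither array.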

Other observations

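The single genes in the first paragraphs, and all tests of explanations, were chosen after the values were seen, so these genes stand for no group. Among genes at least 2-fold higher in knockout skin were Nlrc5, the activator of MHC class I genes, at 580 in control and 1163 in knockout skin, the peptide transporter subunit Tap2 at 883 and 1834, H2-Q8 at 606 and 1328 and H2-T10 at 1046 and 2326. B2m, the light chain of MHC class I, was within 1.5-fold, at 18923 and 22989. The interferon-induced GTPase Igtp was at 536 and 1390 and the adhesion molecule Vcam1 at 600 and 1366. Also past 2-fold were Mgll, a monoglyceride lipase, at 4405 and 9579, the peroxisomal oxidase Acox2 at 796 and 1972, its relative Acoxl at 488 and 1296, the lipoxygenase Alox12e at 1363 and 3426, and the retinol dehydrogenase Rdh9 at 732 and 1779.

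Among genes at least 2-fold lower were the transcription factors Msx1 at 662 and 184, Sp6 at 1473 and 421 and Tfap2b at 917 and 368, and Foxe1 was at least 3.48-fold lower. Nfatc1, a transcription factor of follicle stem cells, went the other way within 1.5-fold, at 747 and 987. Slc40a1, the iron exporter ferroportin, was at 6956 and 2048, and Chac1, a glutathione-degrading enzyme, at 3511 and 743. Eraf, which encodes a stabiliser of alpha haemoglobin, was at least 4.54-fold lower. Within the erythrocyte and platelet list, Alas2, the haem synthesis enzyme of red cells, was at 515 and 295.

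Hair shaft, inner root sheath and melanocyte genes were lower together on the knockout array. The tables argue against the authors' normalization or background handling as the source. In the settings with background correction, the hair follicle median lay between -6.16 and -5.67 and the melanocyte median between -3.86 and -3.35. Over all alternatives the list median closest to 0 was -1.57, for melanocyte genes without a detection filter, a setting that keeps the authors' values. Fewer keratinocytes are not borne out by the basal keratinocyte list, with a median of 0.09 and quartiles of 0.02 and 0.17. Sebaceous gland genes did not fall with the hair genes, their list having a median of 0.78 and quartiles of 0.62 and 1.16. Fewer whole pilosebaceous units stay open, since that list measures total transcript and not the number of glands. The hair cycle stage of the pooled mice cannot be told apart from genotype, because there is 1 array per group and stage may differ between mice of 1 genotype. An effect of genotype, which the design names, stays open and untested. Separating it from stage would take at least replicate arrays of both genotypes with hair cycle stage recorded, not analysed here.

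Interferon-response and MHC class II genes were higher together. Sequence variants at the H2 gene cluster could alter the signal of H2 probes. All 15 detected interferon-list genes lie outside it and were higher, with a median of 0.97 and quartiles of 0.64 and 1.19. These are the values of the whole list, already part of the pattern, so they are no separate check. For the H2 genes themselves such variants stay open. For more leukocytes of every kind, the neutrophil list had a median of 0.12 and quartiles of -0.08 and 0.21. The macrophage list had a median of 0.29 and quartiles of 0.17 and 0.38. These values argue against a rise of every kind as large as that of the interferon genes. A smaller rise stays open, since 8 of 12 neutrophil genes and 12 of 14 macrophage genes were higher. More lymphoid cells in the knockout pool is a candidate explanation. The lymphoid list had a median of 0.81 and quartiles of 0.30 and 0.89, or a median of 0.14 with undetected genes included. Its genes are dim, with Cd3g at 347 and 762, and Lck did not rise, at 270.5 and 260.2. Whether such cells, the genotype or a difference between the pools of mice raised the interferon genes was not separated here.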
